A study of Homo sapiens with 6 samples.

How the data were processed

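Human AZ-521 cells had been exposed to platycodon D (PD), a triterpenoid saponin of the balloon flower, or to its solvent DMSO, and polyadenylated RNA had been sequenced from 3 samples per group. Per the labels' protocols, libraries were made with a stranded mRNA kit from Illumina and read as pairs on a HiSeq machine. The aligner, the counting program and whether counting used the strand are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10. The deposited table holds human genes instead: all 58735 gene identifiers are those of GENCODE release 29 (Ensembl 94, build GRCh38), with the same chromosome, start, end and strand for 58735 of them and 0 mouse identifiers. Coordinates below are those of the table.

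The authors deposited a table of FPKM values (fragments normalised to gene length and to library size), one column per sample, with the gene length beside them. Columns were matched to samples by the group prefix and the number that ends each title. Of the gene names, 27 had been turned into calendar dates by a spreadsheet, and they were replaced through their gene identifiers. The product of FPKM and gene length was, for 100% of the values above 0 in each sample, a whole multiple of one step per sample within a tolerance of 0.01, so whole reads per gene could be recovered. They summed to between 14915538 and 16341687 over all genes, so depth differed little between samples. The FPKM denominators implied by those steps were not the gene totals. They were 1.03, 1.10 and 1.08 times the gene total in DMSO replicates 1 to 3 and 1.00, 0.997 and 0.947 times in PD replicates 1 to 3, so the deposited values carry a scaling between samples whose origin is not given in the sources used here. It lay within 1.01 to 1.02 times of scaling by the median ratio to a reference sample.

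Values were transformed as log2(FPKM + 1), where the pseudocount of 1 understates the change of genes at low FPKM, and 13579 genes with an FPKM of at least 1 in at least 3 samples were kept. PD was compared with DMSO with limma 3.58.1 in R 4.3.3 (mean-variance trend, two-sided moderated test), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05 together with at least a 2-fold change, the thresholds named in the labels. "Rose" and "fell" refer to the adjusted p alone. The comparison had no covariate. These choices, 37 gene lists with 960 genes, the rule for named genes and most alternatives were made before the data were examined. Lists with at least 5 tested members were tested with limma's camera (preset correlation of 0.01 between genes, and an estimated one beside it) and fry, adjusted over the 32 lists tested. List genes were matched through gene identifiers, the table's own names or older synonyms.

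Named genes were the 12 called protein-coding genes with the largest rise and the 12 with the largest fall that had a mean of at least 5 FPKM in the higher group and separate replicates, up to 4 members per described list (called members with the largest change, or those with the highest FPKM where fewer than 2 were called), and a fixed set with CDKN1A, MYC, DDIT3, ATF3, MKI67, CCND1, ACTB and GAPDH. Some genes that this rule takes are not reported here. Lineage markers described follow the list rule. Other genes named are marked as chosen after their values were seen.

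The fits were tested on simulated reads for PD against DMSO drawn from the real means and depths, with 200 changed genes in a run over 13611 genes. In that run, 94% of the 3-fold changes and 26% of the 1.5-fold changes were recovered at an adjusted p under 0.05, and 6.98% of the calls were false. Changed genes were drawn only from tested genes above a minimum mean read number, so the recovered shares leave out the lowest genes. For these shares no GC shift between samples was simulated. All simulated reads were recovered from their FPKM values, and 0 of 31 unchanged lists passed camera. Genes were drawn independently in that run, so it could not show how camera fares where the genes of a list are correlated. Settings varied in turn were the pseudocount, the filter, the scaling between samples, the variance model, the replicate block, the size criterion and the samples used. Chosen after seeing the data were limma's voom on the recovered reads, a correction for transcript GC content by a loess curve with a span of 0.3, a minimum of 10 reads, a fit without DMSO replicate 1 and PD replicate 3 and a fit of protein-coding genes. Count models had been planned for a table of raw counts and were not run on the recovered reads, to which only voom was applied. No sample and no per-sample column was left out. Figures were drawn with matplotlib 3.10.9.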

Results

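This series measured messenger RNA by sequencing in AZ-521 cells, which the labels describe as a gastric cancer line and which cell banks list as derived from a duodenal carcinoma. The stated purpose was to explore how platycodon D acts against gastric cancer cells. Cells received 10 µM platycodon D (PD) or DMSO for 48 h, with 3 samples in each group. Reads over genes numbered 14915538, 15505311 and 16341687 in DMSO replicates 1 to 3 and 15328454, 15401415 and 15821524 in PD replicates 1 to 3. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Pearson correlations of log2(FPKM + 1) between replicates lay between 0.969 and 0.985, and those between groups between 0.920 and 0.944. The first principal component held 59.5% of the variance and separated PD from DMSO. The second, with 18.9%, set DMSO replicate 1 and PD replicate 3 apart from the other samples. Deviations from the group means correlated across genes with transcript GC content in 5 of the 6 samples, downward in these 2 (Spearman rho = -0.61 and -0.50) and upward in DMSO replicates 2 and 3 and PD replicate 1 (0.44, 0.52 and 0.59), against 0.01 in PD replicate 2. Such deviations cancel out within a group by construction, so a shift of a single sample tends to give opposite signs in others of its group.

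The comparison of PD with DMSO asked which genes changed after 48 h. The largest rises among the named genes included INSIG1, which retains the sterol-sensing SREBP complex in the endoplasmic reticulum, and VGF, a secreted neuropeptide precursor. INSIG1 (ENSG00000186480, chromosome 7, 155297776 to 155310235 on GRCh38) rose from 7.64 ± 0.185 to 68.6 ± 4.52 FPKM (SD, n = 3 per group), a log2 fold change of 3.01 ± 0.08 (SE). VGF rose from 59.9 ± 9.80 to 480 ± 17.6 FPKM. TFRC, the transferrin receptor that takes up iron, rose from 7.65 ± 0.208 to 62.1 ± 5.05 FPKM. NR1D1, a circadian repressor, rose from 4.36 ± 0.92 to 37.1 ± 1.38 FPKM, and CLU, an extracellular chaperone, from 9.94 ± 0.423 to 66.8 ± 3.30 FPKM. The Notch ligand DLL1, C7orf57 and the cornified envelope gene LCE1F rose by 2.50, 2.78 and 2.83 on the log2 scale. Among the named genes the largest fall on the log2(FPKM + 1) scale was that of the homeobox gene MEOX2 (ENSG00000106511, chromosome 7, 15611212 to 15686812), from 27.2 ± 3.44 to 2.46 ± 0.166 FPKM, a log2 fold change of -3.02 ± 0.11. SOSTDC1, a secreted antagonist of BMP and Wnt signalling, fell from 13.9 ± 1.05 to 1.77 ± 0.371 FPKM, and the ephrin receptor EPHA7 from 81.1 ± 10.6 to 25.3 ± 1.78 FPKM. The Wnt transcription factor TCF7L2 had a log2 fold change of -1.39, the peroxisomal transporter ABCD2 of -1.62, the scaffold protein MPP7 of -1.49 and the melanocortin receptor MC5R of -1.48. OSR2, MND1 and ANKMY2 had log2 fold changes of -1.47, -1.40 and -1.35. Adjusted p-values of these genes in limma lay between 1.24e-05 for INSIG1 and 0.00307 for MND1.

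Of 13579 genes tested, 386 were called higher and 133 lower in PD, of which 251 and 90 were protein-coding. These counts were 626 and 336 with a pseudocount of 0.1, 667 and 374 with voom on recovered reads, and 227 and 77 at a minimum mean of 5 FPKM. Without the size criterion 1947 genes rose and 1731 fell at an adjusted p under 0.05, 3678 in all. This total was 2235 without DMSO replicate 2, 2230 without DMSO replicate 3, 2423 without PD replicate 1 and 2003 without PD replicate 2, but 3415 without DMSO replicate 1, 3534 without PD replicate 3 and 4558 without both of these. With array weights it was 6301. Called genes that were higher had a median log2 fold change of 1.27, and 41 of them reached 4-fold, against a median of -1.13 and 3 genes for the lower ones. Scaling every sample to the same total moved the median of all genes by -0.13 and gave 280 higher and 248 lower, so that 53% of the calls were higher against 74.4% as deposited. Without DMSO replicate 1 and PD replicate 3 the counts were 439 and 144.

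**Figure D1:**
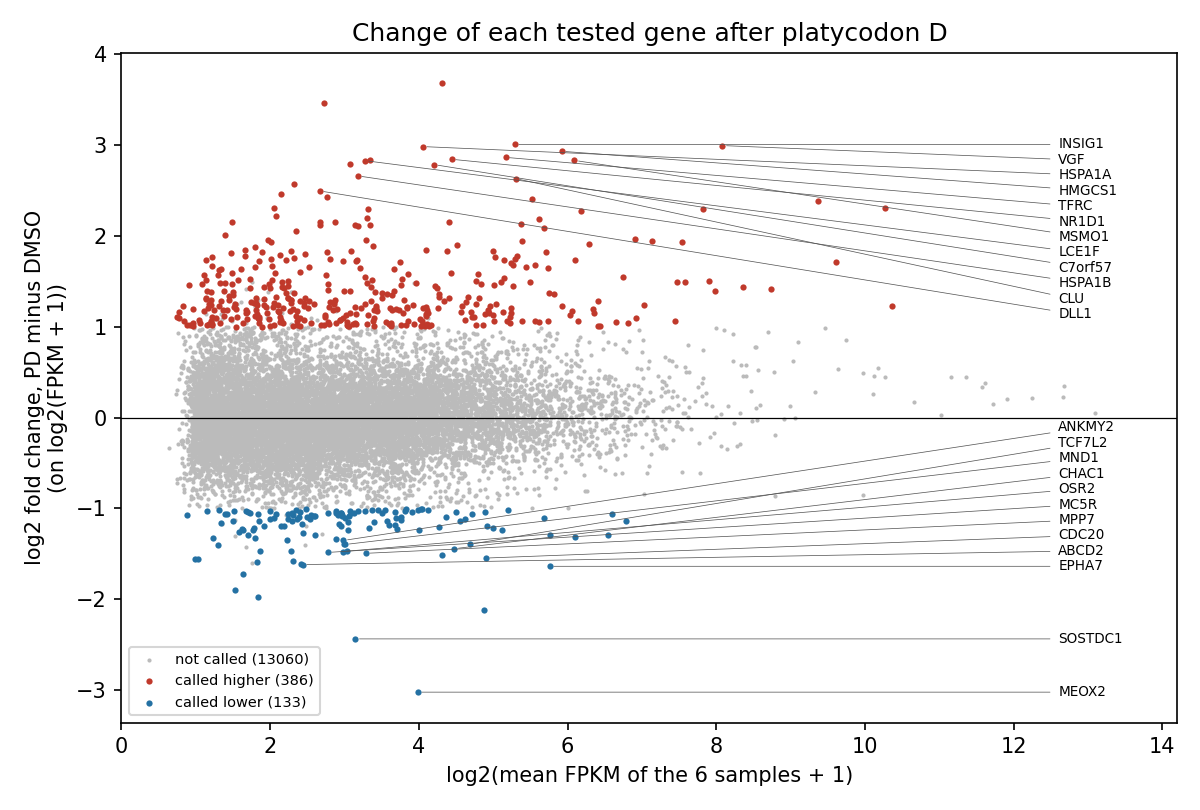
Log2 fold change of PD over DMSO (vertical, on log2(FPKM + 1)) against the log2 mean FPKM of the 6 samples (horizontal) for the 13579 tested genes. Red and blue points are the 386 genes called higher and the 133 called lower, and labels mark the 12 named genes at each end, from INSIG1 at 3.01 to MEOX2 at -3.02.

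Genes of sterol synthesis and uptake rose together. Of the 24 tested members of that list 20 rose and 0 fell, 18 of them at least 2-fold, and 21 rose adjusted over the list alone. HMGCS1, which makes the precursor of mevalonate, rose from 13.1 ± 1.77 to 106 ± 4.02 FPKM (SD, n = 3). MSMO1, a sterol demethylating enzyme, rose from 15.8 ± 1.91 to 119 ± 12.4 FPKM. Their adjusted p-values were 2.33e-05 and 2.73e-05. In the fatty acid synthesis list 10 of 12 rose, and 11 did so adjusted over the list alone. The desaturase SCD rose from 211 ± 11.2 to 1104 ± 15.1 FPKM, and LPIN1 and FASN had log2 fold changes of 1.13 ± 0.08 and 1.12 ± 0.14. The camera test gave an adjusted p of 1.36e-15 for the sterol list and adjusted p = 0.0804 with an estimated correlation. For the fatty acid list it gave 2.19e-07, and adjusted p = 0.0984 with an estimated correlation.

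Lysosomal genes formed the list whose test also passed with an estimated correlation (adjusted p = 3.2e-14 with the preset and adjusted p = 0.0237 with the estimated correlation). Of 40 tested members 30 rose and 1 fell, and 31 rose and 1 fell adjusted over the list alone. GLA, which encodes alpha-galactosidase, rose from 13.7 ± 0.317 to 49.3 ± 2.10 FPKM, and CTSA, a protective carboxypeptidase, from 15.3 ± 1.96 to 53.2 ± 3.51 FPKM (SD, n = 3). NPC1, which exports cholesterol from lysosomes, rose from 24.9 ± 0.725 to 79.9 ± 3.76 FPKM, and the lysosomal channel gene MCOLN1 from 11.1 ± 1.78 to 29.2 ± 4.28 FPKM. The member that fell was MITF, a transcription factor of the family that drives lysosomal genes, with a log2 fold change of -0.79 (adjusted p = 0.00488), named after its value was seen. In the autophagy list 17 of 31 rose and 0 fell, and 18 rose adjusted over the list alone. SQSTM1, an autophagy receptor, rose from 57.0 ± 3.50 to 222 ± 15.8 FPKM. BNIP3, WIPI1 and GABARAPL1, which act in mitophagy and autophagosome formation, had log2 fold changes of 1.42, 1.27 and 1.24. That list had an adjusted p of 4.2e-07, and adjusted p = 0.0984 with an estimated correlation.

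Oxidative stress and chaperone genes rose as well. In the NRF2 target list 12 of 18 rose and 0 fell, and 13 rose and 1 fell adjusted over the list alone. HMOX1, which degrades heme, rose from 415 ± 53.1 to 2055 ± 295 FPKM, and TXNRD1, a thioredoxin reductase, from 29.1 ± 1.03 to 76.7 ± 2.02 FPKM (SD, n = 3). The ferritin genes FTH1 and FTL had log2 fold changes of 1.93 ± 0.24 and 1.23 ± 0.14, and FTL did not pass with no filter (adjusted p = 0.0538). In the heat shock list 12 of 19 rose and 0 fell, and 12 rose and 1 fell adjusted over the list alone. HSPA8 rose from 19.8 ± 0.95 to 64.8 ± 5.05 FPKM, and the small heat shock gene CRYAB from 3.66 ± 0.565 to 11.2 ± 0.451 FPKM. HSPA1A and HSPA1B had log2 fold changes of 2.98 ± 0.15 and 2.66 ± 0.15. The camera test gave 3.39e-06 for NRF2 targets and 8.42e-07 for heat shock, and adjusted p = 0.0984 and adjusted p = 0.121 with an estimated correlation. In the ferroptosis list 7 of 17 rose and 1 fell, also adjusted over the list alone, with TFRC, HMOX1, FTH1 and FTL among the 7 and the glutathione-degrading enzyme CHAC1 as the one that fell. Its test gave 0.00753, and adjusted p = 0.177 with an estimated correlation.

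Among 22 endoplasmic reticulum chaperone genes 8 rose and 1 fell, and 10 rose and 1 fell adjusted over the list alone. HSPA5, the main chaperone of that compartment, rose from 268 ± 6.04 to 463 ± 47.1 FPKM (SD, n = 3), and CALR had a log2 fold change of 0.43 ± 0.10 (adjusted p = 0.0222). XBP1, a transcription factor of the unfolded protein response, was the member that fell (-0.46, adjusted p = 0.0342), named after its value was seen. It did not pass without DMSO replicate 1 or 3 or PD replicate 1 or 2 (adjusted p = 0.073, 0.0919, 0.107 and 0.115), nor with no filter (0.0857). CANX and HSP90B1 stood at 0.12 and 0.19 without passing the test, and HSP90B1 passed with array weights (adjusted p = 0.0367). CANX turned negative under quantile and equal total scaling. In the proteasome list 14 of 29 rose and 0 fell, 0 of them by 2-fold, and 15 rose adjusted over the list alone, with PSMC4 at 0.60 and PSMB7 at 0.38 (adjusted p = 0.0254). PSMB4 and PSMA7 stood at 0.28 and 0.01 without passing, and PSMA7 turned negative under each other scaling. CALR did not pass with equal totals, under quantile scaling or without DMSO replicate 2 or PD replicate 1 or 2 (adjusted p = 0.108, 0.0547, 0.080, 0.0755 and 0.0647), nor with no filter (0.058). PSMB7 did not pass with equal totals (0.103), under quantile scaling (0.0571), with no filter (0.0542), without any replicate but PD replicate 2 (0.0503 to 0.0824) or without DMSO replicate 1 and PD replicate 3 (0.0523). With equal totals 2 of the chaperone genes and 5 of the proteasome genes rose. The tests gave 0.00395 for the chaperones and 6.95e-05 for the proteasome, with adjusted p = 0.227 and adjusted p = 0.316 with an estimated correlation.

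Immediate early genes, which answer growth and stress signals within minutes to hours, rose in 21 of 29 cases and fell in 0, with 21 rising adjusted over the list alone. FOS rose from 2.30 ± 0.0627 to 13.3 ± 0.796 FPKM, NR4A3 from 2.54 ± 0.431 to 15.2 ± 1.58 FPKM and KLF2 from 8.41 ± 3.03 to 31.1 ± 0.174 FPKM (SD, n = 3). FOSB had a log2 fold change of 2.22 ± 0.12. ATF3, also on this list, stood at 0.11 (adjusted p = 0.406) and turned negative under quantile and equal total scaling. The list test gave 1.32e-11, and adjusted p = 0.0984 with an estimated correlation. In the NF-kB and inflammatory list 9 of 16 rose and 0 fell, also adjusted over the list alone. The cytokine LIF rose from 23.8 ± 2.59 to 119 ± 10.9 FPKM, and BIRC3, an inhibitor of apoptosis, from 6.43 ± 1.12 to 25.8 ± 4.43 FPKM. IL32 and TNFAIP3 had log2 fold changes of 1.39 and 1.18. The test gave 0.000373, and adjusted p = 0.177 with an estimated correlation.

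Genes of cell division fell. Of 40 tested members of the G2/M and mitosis list 34 fell and 0 rose, 14 of them at least 2-fold, and 38 fell adjusted over the list alone. CDC20, which activates the anaphase-promoting complex, fell from 43.4 ± 4.46 to 14.3 ± 2.32 FPKM, and TOP2A, a topoisomerase, from 76.5 ± 19.7 to 30.2 ± 5.60 FPKM (SD, n = 3). HMMR and the proliferation marker MKI67 had log2 fold changes of -1.22 ± 0.21 and -1.18 ± 0.08. In the G1/S and replication list 21 of 35 fell and 0 rose, and 26 fell and 1 rose adjusted over the list alone. PCNA, the sliding clamp of replication, fell from 63.1 ± 3.27 to 39.8 ± 3.20 FPKM, and MCM6 had a log2 fold change of -0.34 (adjusted p = 0.0173). MCM6 did not pass without DMSO replicate 2 or 3 or PD replicate 1 or 2 (adjusted p = 0.0591, 0.061, 0.0571 and 0.0717). RRM1 and SLBP stood at -0.15 and 0.09 without passing the test. RRM1 passed with equal totals (adjusted p = 0.0344), and SLBP turned negative under quantile and equal total scaling. In the DNA repair list 14 of 23 fell and 0 rose, and 15 fell adjusted over the list alone. PARP1 had a log2 fold change of -0.34 (adjusted p = 0.0182), while TOPBP1 and ATM stood at -0.30 and 0.24 without passing. PARP1 did not pass without DMSO replicate 2 or 3 or PD replicate 2 (adjusted p = 0.0649, 0.0776 and 0.080). TOPBP1 passed with equal totals and after GC correction (0.0269 and 0.0200). ATM passed without DMSO replicate 1 (0.0465), with array weights (0.0068), after GC correction (0.041) and without DMSO replicate 1 and PD replicate 3 (0.035). The DNA repair list did not pass at a minimum mean of 5 FPKM (adjusted p = 0.0549). The tests gave 1.52e-17, 4.48e-08 and 3.33e-05 for these lists, and adjusted p = 0.13, adjusted p = 0.121 and adjusted p = 0.168 with an estimated correlation. The cell cycle inhibitor CDKN1A rose from 78.7 ± 4.48 to 107 ± 10.3 FPKM (adjusted p = 0.0212), and CCND1 stood at 86.1 ± 4.37 and 104 ± 4.85 FPKM (adjusted p = 0.0567). CDKN1A did not pass with equal totals (adjusted p = 0.0738) or without DMSO replicate 2 or 3 or PD replicate 1 (adjusted p = 0.0674, 0.051 and 0.073), nor with no filter (0.055) or without DMSO replicate 1 and PD replicate 3 (0.0538), over a range from 0.0097 to 0.0738 across all settings.

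**Figure D2:**
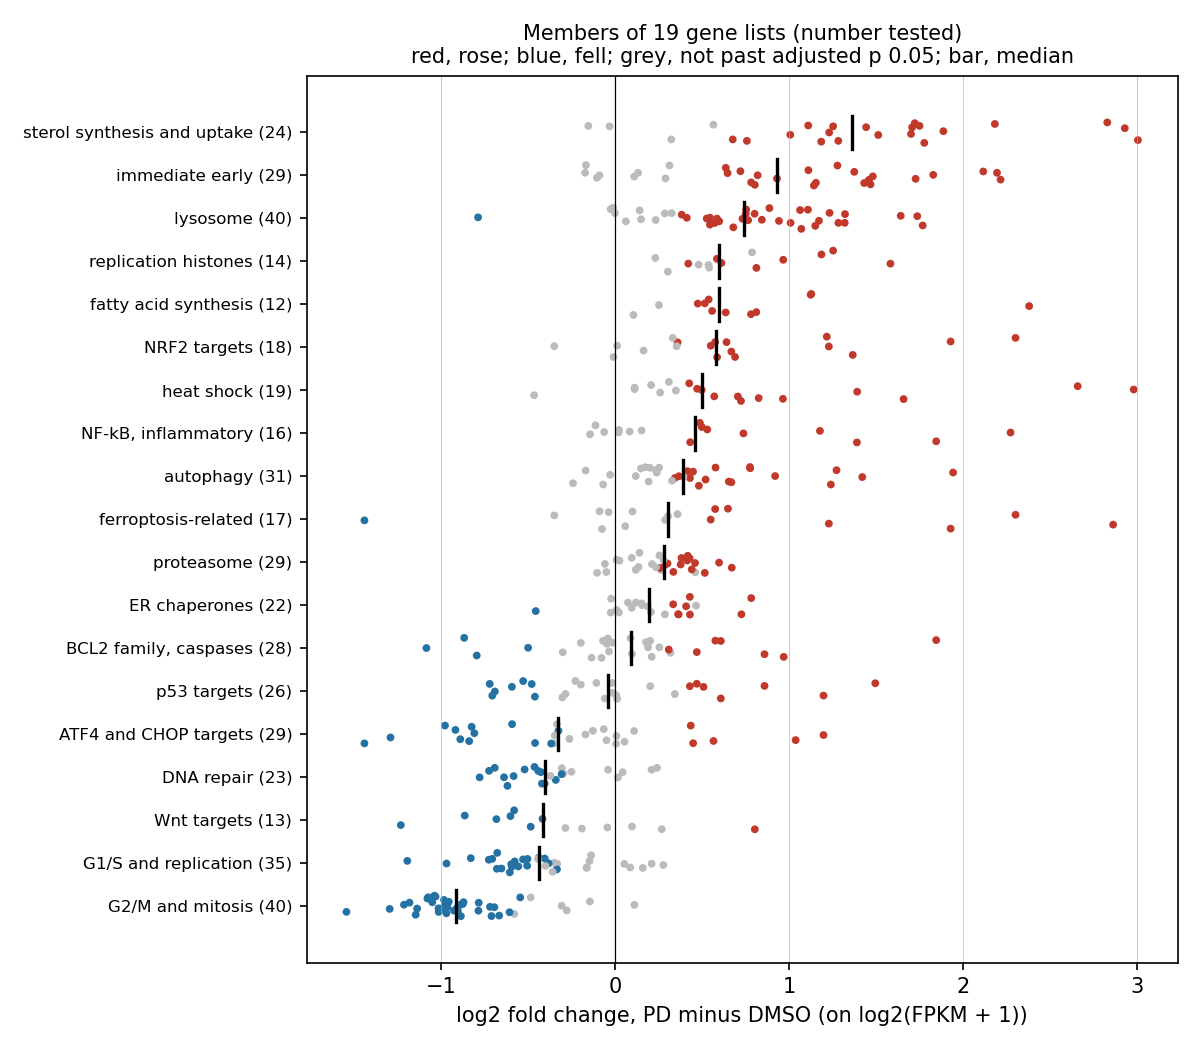
Log2 fold change of PD over DMSO (horizontal) for the tested members of 19 gene lists (listed down the side, number tested in parentheses), each point a gene and each bar the list median. Red points rose and blue points fell at an adjusted p under 0.05, from 20 of 24 sterol genes that rose at the top to 34 of 40 G2/M genes that fell at the bottom.

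Members of the ATF4 and CHOP list, genes of the integrated stress response, went both ways: 5 of 29 rose and 12 fell, and 5 rose and 14 fell adjusted over the list alone. The secreted factor GDF15 rose from 48.8 ± 11.3 to 111 ± 9.88 FPKM, and PPP1R15A, which promotes dephosphorylation of eIF2 alpha, from 72.9 ± 12.1 to 150 ± 20.6 FPKM (SD, n = 3). DDIT3, which encodes CHOP, rose from 141 ± 4.16 to 209 ± 10.5 FPKM. The amino acid transporter subunit SLC3A2 and the tRNA synthetase GARS also rose (0.45 and 0.43), both named after their values were seen. GARS did not pass under quantile scaling or without DMSO replicate 2 or 3 or PD replicate 2 (adjusted p = 0.31, 0.0939, 0.0799 and 0.0664), nor with no filter (0.0878). CHAC1 fell from 31.7 ± 6.86 to 10.9 ± 0.692 FPKM, and PSAT1 from 131 ± 9.23 to 53.1 ± 7.09 FPKM. PSAT1 belongs to serine synthesis, and the other enzymes of that route, PHGDH and PSPH, had log2 fold changes of -0.89 and -0.92 (adjusted p = 0.00133 and 0.000884), both named after their values were seen. Of the 17 members past the test, 16 kept their direction and passed under quantile scaling and 17 under both other scalings and after GC correction. The list test gave 0.00542 downward, and adjusted p = 0.381 with an estimated correlation. In the Wnt target list 7 of 13 fell and 1 rose, and 8 fell and 2 rose adjusted over the list alone. The Wnt antagonist DKK1 fell from 567 ± 34.2 to 312 ± 42.8 FPKM, and the member that rose was MYC, from 142 ± 18.3 to 248 ± 13.9 FPKM. TNFRSF19 and CCND1 stood at -0.05 and 0.27 without passing. Under quantile scaling TNFRSF19 passed at -0.29 (adjusted p = 0.0172), and CCND1 passed under upper quartile scaling, with array weights and with voom (0.0473, 0.0238 and 0.0486). Its test gave 0.00753, and adjusted p = 0.191 with an estimated correlation.

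In the p53 target list 7 of 26 rose and 7 fell, and 8 and 9 adjusted over the list alone, but 4 rose and 9 fell with equal totals. GADD45A, a growth arrest gene, rose from 92.1 ± 9.26 to 261 ± 13.3 FPKM (SD, n = 3), as did GDF15 above. The list median was -0.04 and the mean 0.03, and the test pointed down without passing (adjusted p = 0.801). Among BCL2 family and caspase genes 7 of 28 rose and 4 fell, and 8 and 4 adjusted over the list alone (list adjusted p = 0.324), but 4 rose and 6 fell with equal totals. BIRC3 rose as given above, and the pro-apoptotic BIK fell from 7.13 ± 0.57 to 2.93 ± 1.12 FPKM. CASP6, BCL2L1 and APAF1 also fell (-0.87, -0.80 and -0.50), named after their values were seen. APAF1 did not pass without PD replicate 1 or 2 (adjusted p = 0.0559 and 0.0665). Replication-dependent histone genes rose in 8 of 14 cases and fell in 0, with 11 rising adjusted over the list alone. HIST1H3B rose from 6.29 ± 1.63 to 20.6 ± 2.80 FPKM, and HIST1H1C and HIST1H4H had log2 fold changes of 1.25 ± 0.15 and 1.19 ± 0.11. Their list test gave 1.22e-05, and adjusted p = 0.0866 with an estimated correlation.

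**Figure D3:**
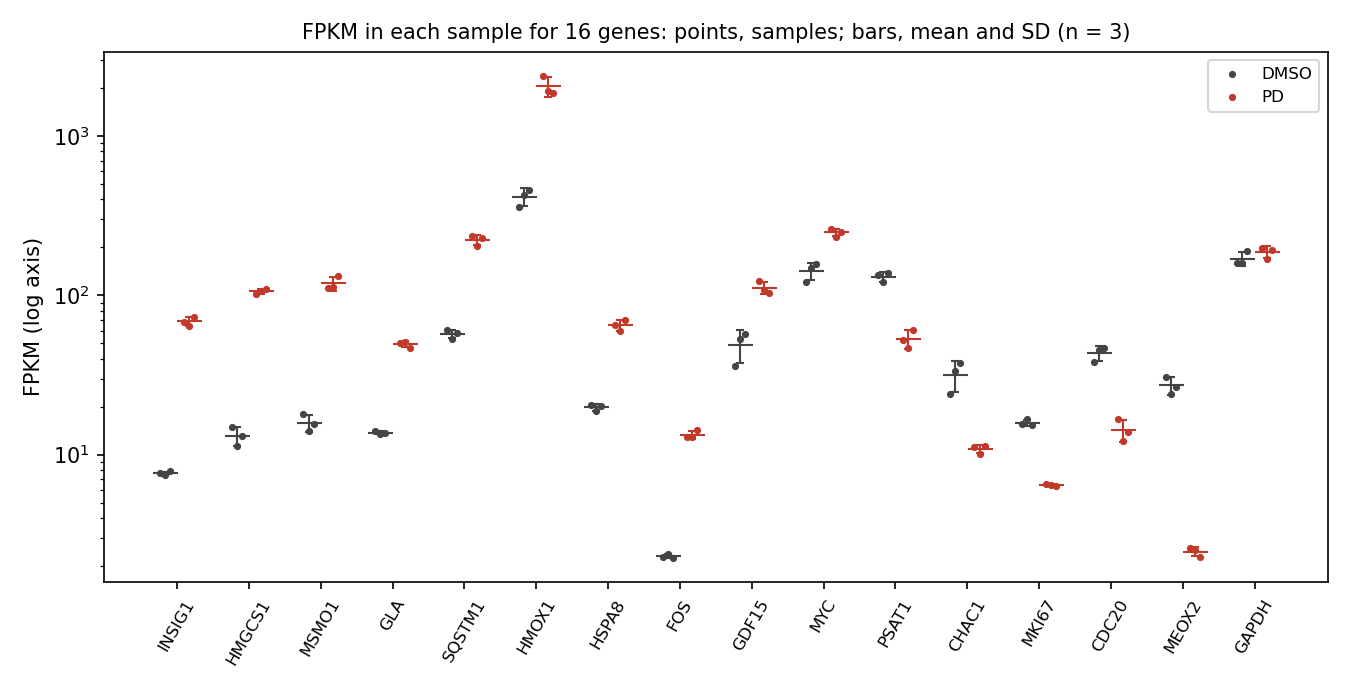
FPKM on a log axis for 16 genes, with DMSO samples in grey and PD samples in red, each point a sample and each bar the mean with its SD (n = 3). The PD samples of INSIG1 average 68.6 FPKM against 7.64 in DMSO, and those of MEOX2 2.46 against 27.2.

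Other lists did not pass camera. Their counts of members that rose and fell were 10 and 2 of 25 for hypoxia and glycolysis (12 and 3 adjusted over the list alone, list adjusted p = 0.0732) and 7 and 2 of 16 for YAP targets (7 and 3 alone, 0.0706). They were 8 and 4 of 18 for matrix and mesenchymal genes (10 and 4 alone, 0.0985) and 5 and 4 of 17 for TGF-beta targets (5 and 4 alone, 0.429). Growth factor receptor and mTOR genes gave 5 and 5 of 25 (5 and 6 alone, 0.891), with a median of 0.01, a mean of 0.02 and a downward test direction. Interferon response genes gave 3 and 4 of 22 (3 and 4 alone, 0.225). Cell cycle inhibitors and D cyclins gave 3 and 5 of 16 (4 and 5 alone, 0.429). Genes of MYC and ribosome biogenesis gave 3 and 1 of 32 (3 and 1 alone, 0.183), ribosomal proteins 1 and 1 of 74 (0 and 0 alone, 0.801), nuclear oxidative phosphorylation genes 4 and 1 of 39 (4 and 0 alone, 0.196) and mitochondrially encoded genes 1 and 0 of 13 (0 and 0 alone, 0.0907). The matrix and mesenchymal list passed with equal totals and at a filter of 0.1 FPKM (adjusted p = 0.0431 and 0.0497). With voom the hypoxia, YAP and mitochondrial lists passed (0.0441, 0.0443 and 0.0392), the last also with array weights (0.0462). The hypoxia list passed without DMSO replicate 3 or PD replicate 2 (adjusted p = 0.0467 and 0.0388), YAP targets without DMSO replicate 1 (0.0442), oxidative phosphorylation without PD replicate 2 (0.0409) and mitochondrial genes without DMSO replicate 1 or PD replicate 1 (0.0442 and 0.00737). Ribosomal proteins passed downward under quantile scaling (adjusted p = 0.0355), with 0 rising and 14 falling. With equal totals the counts that rose and fell were 6 and 5 for hypoxia, 6 and 4 for YAP targets, 8 and 5 for matrix genes, 4 and 4 for TGF-beta targets and 4 and 9 for growth factor receptor genes. They were 3 and 8 for interferon genes, 2 and 9 for cell cycle inhibitors, 3 and 5 for MYC, 0 and 8 for ribosomal proteins, 1 and 3 for oxidative phosphorylation and 0 and 0 for mitochondrial genes. Among 4 tested LXR targets APOE, SMPDL3A and SREBF1 rose (3 genes, also adjusted over the list alone), a list too small for the test. SMPDL3A did not pass under quantile scaling (adjusted p = 0.0526), with no filter (0.0818), with the replicate block (0.0843) or without any replicate but DMSO replicate 1 (0.0617 to 0.0922). SREBF1 did not pass with equal totals (0.0569) or with the replicate block (0.0634). ACTB rose from 270 ± 19.3 to 404 ± 38.6 FPKM (adjusted p = 0.00896) but not under quantile scaling or with no filter (adjusted p = 0.0966 and 0.0569). GAPDH stood at 170 ± 16.9 and 187 ± 15.5 FPKM (adjusted p = 0.381) and turned negative under quantile and equal total scaling.

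Lineage and other cell types were measured through marker lists. Of 21 gastric markers 18 stayed under 1 FPKM in every library, as did 21 of 22 intestinal, 12 of 13 immune and 12 of 17 stromal markers. SOX2 stood at 38.9 ± 1.70 FPKM in DMSO and 34.4 ± 3.05 in PD, and CDX2 at 1.27 ± 0.296 and 1.18 ± 0.238 (SD, n = 3). Of the 2 gastric markers tested, MUC1 rose with a log2 fold change of 0.43 (adjusted p = 0.0453). MUC1 did not pass with equal totals (adjusted p = 0.144), under upper quartile scaling (0.0697), with no filter or one of 0.1 FPKM (0.113 and 0.074) or without DMSO replicate 1 or 3 or PD replicate 1 or 2 (0.0969, 0.125, 0.117 and 0.146). COL3A1, a fibrillar collagen, stood at 42.9 ± 3.81 and 40.6 ± 1.32 FPKM, and 0 of 5 tested stromal markers passed (list adjusted p = 0.133). Under quantile and upper quartile scaling and with voom 1 stromal marker fell. With equal totals, after GC correction and without DMSO replicate 1 and PD replicate 3, 2 fell. Of 25 epithelial junction genes 17 stayed under 1 FPKM in every library, among them CDH1, EPCAM and KRT8, named after their values were seen. How reads fitting several genes were counted is not given, so such low values do not by themselves show absence of expression. Of the 7 tested junction genes 1 rose and 2 fell (1 and 3 adjusted over the list alone, list adjusted p = 0.68). The single tested metallothionein, intestinal and immune markers MT2A, CDX2 and CD8A did not pass, while CD8A (-0.23) and SOX2 (-0.17) passed with equal totals (adjusted p = 0.0417 and 0.0381), and CD8A with array weights and after GC correction (0.0229 and 0.0259).

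Values of HSPA1A and HSPA1B, FTH1 and FTL, LCE1F and the histone genes are uncertain, since they have near-identical copies or pseudogenes and how reads fitting several genes were counted is not given, as are NR1D1, DLL1, SQSTM1, FOSB, LIF, CTSA, NPC1, BNIP3, DDIT3, DKK1, CCND1, SREBF1, MCOLN1, TXNRD1, WIPI1, GDF15, ATM and HSP90B1, whose spans overlap another expressed gene. The preset-correlation list test called 6 to 18 lists when the 6 samples were regrouped into other sets of 3, against 17 for PD and DMSO, and 25 of 32 lists passed fry, which tests whether genes move on balance one way.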

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

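The voom fit, the GC correction, the read minimum, the fit without DMSO replicate 1 and PD replicate 3 (the pair below) and the protein-coding fit were chosen after the data were seen; the other tests were planned. Leaving out each replicate in turn gave 341 to 446 genes higher, 122 to 162 lower, 2003 to 3534 at the adjusted p alone and 17 to 19 lists. The count at the adjusted p alone depended on which sample was left out: it was 2235 without DMSO replicate 2, 2230 without DMSO replicate 3, 2423 without PD replicate 1 and 2003 without PD replicate 2, but 3415 without DMSO replicate 1, 3534 without PD replicate 3 and 4558 without these last 2. No pairing of samples by replicate number was visible (correlations of deviations of -0.39, 0.17 and -0.16 for numbers 1 to 3). Deviations cancel out within a group by construction, so these values cannot exclude a pairing. With the replicate block 380 genes were higher, 132 lower and 1844 changed at the adjusted p alone. With this block 11 named genes no longer passed limma (adjusted p = 0.0634 to 0.0905). They were XBP1, CALR, PSMB7, MCM6, PARP1, CDKN1A, GARS, APAF1, SREBF1, SMPDL3A and MUC1. A pseudocount of 0.1 gave 626 higher and 336 lower, and one of 0.5 gave 218 lower, since a smaller pseudocount shrinks low genes less. A minimum mean of 5 FPKM gave 227, 77 and 2214, with fewer genes tested (7380), and protein-coding genes alone gave 252 higher. Equal totals gave 248 lower, since this scaling lowers PD values against DMSO, with a median over all genes of -0.13. Array weights gave 6301 at the adjusted p alone. The voom fit on recovered reads gave 667 higher and 374 lower, of which 377 and 126 were also called as deposited. For array weights and voom the cause was not tested. A test against a 2-fold change itself left 60 higher and 2 lower, a stricter criterion by construction. With an estimated correlation 1 list passed, that of the lysosome. GC correction gave 346 higher and 153 lower, and the fit without DMSO replicate 1 and PD replicate 3 gave 439 and 144, sharing 352 and 107 with the calls from all samples. Count models, planned for a table of raw counts, were not run on the recovered reads.

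Direction (for lists, that of the test) turned for results that had not passed the test. Ribosomal protein medians were -0.090 under quantile scaling (adjusted p = 0.0355), -0.12 with equal totals, -0.072 with array weights and -0.063 without the pair. At a minimum mean of 5 FPKM the median was 0.044 and the test pointed down. The mitochondrial list had a median of 0 under quantile scaling. PSMA7 stood at -0.12 (quantile), -0.020 (upper quartile), -0.15 (equal totals), -0.12 (array weights), -0.027 (GC corrected) and -0.10 (without the pair). GAPDH stood at -0.081 and -0.020, CANX at -0.18 and -0.042, ATF3 at -0.016 and -0.051, and SLBP at -0.0066 and -0.072 under quantile and equal total scaling, with SLBP at -0.0050 without the pair. Without single replicates p53 targets ranged from -0.11 to 0.0036, ribosomal proteins from -0.031 to 0.11, growth factor receptor genes from -0.015 to 0.047, SLBP from -0.021 to 0.15, PSMA7 from -0.049 to 0.087, TNFRSF19 from -0.093 to 0.0048, CDX2 from -0.15 to 0.038 and ETV1 from -0.14 to 0.042. COL3A1 stood at 0.0016 without the pair. Equal total and upper quartile scaling multiply all genes of a sample by one factor, so turns of values near 0 there follow by construction; the cause of the other turns was not tested. Of the named gene values under the alternatives, 2357 kept direction and side of the threshold, 70 no longer passed, 16 newly passed and 24 turned; of list values 695 kept both, 17 no longer passed (16 with an estimated correlation), 12 newly passed and 11 turned. At 14915538 to 16341687 reads, simulated 1.5-fold changes of genes above a minimum mean read number were recovered in 26% of cases. The simulated run had far fewer changed genes than the 3678 that passed the adjusted p here. Passing the adjusted p therefore needed a smaller unadjusted p in the simulated run. The 26% is thus not the share of such changes recovered in PD against DMSO. How many small changes were missed there was not measured, which limits statements on them.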

Other observations

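The tests of library depth, of neighbouring genes and of the sterol and fatty acid lists were chosen after their results were seen; the others were written before. Several of the most lowered genes lie near each other on the short arm of chromosome 7. Between 15611212 and 16784536 (GRCh38), a stretch of 1173325 bases from MEOX2 to TSPAN13, all 7 tested genes fell and 6 fell at least 2-fold. Not all of the 7 protein-coding genes listed in the stretch were tested, and no tested gene lay between 15695491 and 16461481. MEOX2 and SOSTDC1 had log2 fold changes of -3.02 and -2.44, ANKMY2, TSPAN13 and BZW2 of -1.35, -1.10 and -0.47, and the noncoding genes LINC02587 and AC005550.1 of -1.72 and -1.90. The flanking tested protein-coding genes ETV1 and SNX13 stood at -0.07 and 0.13 and did not pass (adjusted p = 0.701 and 0.516). The stretch and its genes were singled out after their values were seen, and the bounds of its tests were set after that. The window of 5 genes with the highest mean, 1.44 on chromosome 1 (DYRK3 to CD55), was matched or exceeded in 58 of 10000 random gene orders.

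This stretch held the lowest mean log2 fold change of any 5 consecutive tested protein-coding genes (-1.68, over 10556 windows), and 0 of 10000 random gene orders gave a window as low, the lowest being -1.35, which argues against a chance position of unrelated genes. After GC correction all 7 genes were still lower at an adjusted p under 0.05, and the 6 at least 2-fold lower remained so, which argues against GC content as the whole cause. Loss of copies of the whole stretch in part of the cells would lower its genes by a common factor. Yet the log2 ratios of BZW2 and MEOX2, taken on mean FPKM without the pseudocount, differed by 2.94 ± 0.11 (SE). Loss of the whole stretch thus cannot be the whole cause. This comparison cannot exclude a loss of part of the stretch. PD over DMSO ratios were 0.090, 0.118, 0.058 and 0.127 for MEOX2, LINC02587, AC005550.1 and SOSTDC1. They were 0.333, 0.695 and 0.451 for ANKMY2, BZW2 and TSPAN13. A candidate explanation is shared regulation of the stretch under PD, a hypothesis that was not tested; reads shared between the overlapping noncoding genes stay open for those members.

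Replication-dependent histone genes rose while genes of division and replication fell. Their median log2 fold change of 0.60 lay at the 99.99th percentile of 10000 random lists matched on length and level, which argues against gene length and level, and GC correction left it at 0.59. Carry-over of RNA without a poly(A) tail cannot be told apart, since 39 short structural RNA genes had a median of 0.17 with a 95% bootstrap interval of -0.10 to 0.38, too wide to decide. A change in histone tail processing under PD may also apply and was not tested.

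DMSO replicate 1 and PD replicate 3 deviated from their group means together (correlation across genes 0.38). Their mean deviation correlated with transcript GC (Spearman rho = -0.62), and a GC correction lowered the correlation to 0.24, above the 0.1 set beforehand, so GC content may account for part of it and the rest stays open. DMSO replicates 2 and 3 and PD replicate 1 deviated the other way (Spearman rho = 0.44, 0.52 and 0.59). Deviations within a group cancel out by construction, so these signs cannot show whether a GC shift was particular to the pair. The test of library depth met neither of its bounds: DMSO replicate 1 had the fewest reads over genes (14.9 M), while PD replicate 3 had 15.8 M, above the median of 15.5 M. The pair thus lay on opposite sides of the median in depth, but with neither bound met the test cannot decide on depth. DMSO replicate 1 and PD replicate 3 had the fewest genes with a read, 24162 and 24317. The other samples had 25102 to 25809, and whether this relates to the common deviation was not tested. No biological explanation was tested. The fold changes of PD over DMSO correlated little with GC (Spearman rho = 0.07 across genes, which are not independent replicates).

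Of the 10 splits of the 6 samples into 3 and 3, 1 gave as many genes higher (386, highest other 1), 1 as many lower (133, highest other 1) and 1 as many at the adjusted p alone (3678, highest other 1). A split and its mirror image counted as one, so the single gene of the split that grouped DMSO replicate 1 with PD replicates 2 and 3, which was lower as grouped, counted in either direction. For lists 3 splits gave 17 or more (highest other 18). The real grouping into PD and DMSO was 1 of these 3, and it was the 1 split counted for each gene result above. Every mixed split still holds part of the PD effect. With 10 splits no share under 0.05 is possible.

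Sterol genes rose more than fatty acid genes on average, with mean log2 fold changes of 1.40 and 0.78, a difference of 0.63 (two-sided permutation of list membership, p = 0.0261, across genes that are not independent). The test restates the observation it came from, so a response led by the sterol branch of the SREBF targets stays an untested hypothesis.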
